A study of Saccharopolyspora erythraea with 8 samples.

How the data were processed

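RNA was sequenced from 8 liquid cultures of Saccharopolyspora erythraea, 2 for each combination of strain (E3 or EA) and time (10 h or 48 h). Per the labels' protocols, cells were put into RNAlater, disrupted with glass beads, and total RNA was purified with a Qiagen column kit and treated with DNase. Ribosomal RNA was removed with a Ribo-Zero kit for bacteria, and libraries were made with dUTP in the second strand, which was then degraded, so that strand information was kept. The aligner, the counting program and the genome build are not given in the sources used here.

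Each library had 1 deposited table of 7168 coding sequences (CDS). The first unit, per the file headers, was expected counts (Raw Read Count), in which every value was whole or midway between whole numbers, the latter for 34.0% to 37.3% of the values of a library. The second deposited unit was a signal (Raw Transcript Count), which equalled the reads per 100 bases of a CDS and was not scaled to depth. The authors also gave RPKM, reads scaled to CDS length and library depth, and TPM, length-scaled reads brought to the same total in each library. Only the expected counts were used here. They were rounded to whole numbers for the tests. Of the CDS, 6721 carried a locus tag and 447 did not; the latter held 1.71% to 2.84% of a library's reads, were kept, and are named by start and end. A tag was found in the reference gene table for 6671 CDS, of which 812 had a symbol there; both ends were equal for 5584 of the 6671 and at least 1 end for 6659. Positions are those of the deposited tables.

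Changes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with the 4 groups, glmQLFit with a mean per group over all 8 libraries and glmQLFTest, which left 4 residual degrees of freedom and 6.62 prior degrees of freedom. The common biological coefficient of variation was 0.117. Filtering kept 7118 CDS, and p values were adjusted over these by Benjamini and Hochberg; a gene is called changed, higher or lower at an adjusted p under 0.05. Log2 fold changes are given with their standard error, computed as the absolute fold change over the square root of F. Expression is given as CPM, read counts scaled to the TMM-adjusted library size, as mean and SD of 2 libraries. The 5 comparisons were EA with E3 at 10 h, EA with E3 at 48 h, 48 h with 10 h in each strain, and the interaction, which is the strain difference at 48 h minus that at 10 h.

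The tests, the comparisons, 25 gene lists and the rule for named genes were chosen before the data were examined. The rule took every ATP synthase gene. It took up to 8 genes per direction in the strain comparisons and the E3 phase comparison, and up to 4 in the others. These were the genes with the largest absolute log2 fold change among those that passed, did not overlap between replicates (not asked of the interaction), averaged 20 CPM or more and had an informative product. It also took up to 4 members of each list that had any past the threshold, or up to 2 by abundance; other genes named were chosen after their values were seen. The lists were erythromycin biosynthesis, ATP synthase, complex I, other respiratory chain, glycolysis and gluconeogenesis, pentose phosphate pathway, TCA cycle with pyruvate dehydrogenase and glyoxylate, propionyl-CoA and methylmalonyl-CoA supply, branched-chain amino acid degradation, fatty acid beta-oxidation, ribosomal proteins, translation factors with aminoacyl-tRNA synthetases, purine and pyrimidine biosynthesis, nitrogen assimilation, phosphate response, chaperones and proteases, oxidative stress, iron and siderophore, other secondary metabolism, sugar uptake, development and sporulation, sigma and anti-sigma factors, cell division and wall, mobile elements, and rRNA with tRNA. The last list matched 0 CDS, because the tables hold coding sequences alone. Words that matched the wrong products were removed from the matching after values had been seen, to bring the lists closer to their wording. The list for propionyl-CoA and methylmalonyl-CoA supply still holds genes annotated as acetyl-CoA carboxylase subunits, which its wording did not name. Each list has its counts of members past the gene test over all genes and adjusted over the list alone, and camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison.

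Alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, a fold change of at least 2, the 4 compared libraries alone, and camera with an estimated correlation. With a library left out, its group keeps 1 library, which is assumed to vary like the other groups. After the data were seen, library size alone, upper-quartile factors, a fit without untagged CDS and a fit without CDS almost unread in EA were added. A pseudocount alternative fixed for normalised values did not apply to counts. The method was tested on simulated data with the depths of the 10 h comparison. There edgeR recovered 44% of genes changed 1.5-fold, 72% at 2-fold, 96% at 4-fold and 100% at 8-fold, with 12 false calls among 6991 genes; DESeq2 recovered 50%, 68%, 92% and 100%, with 18 among 7118. Of 21 simulated lists of 20 genes, the 1 raised list was called and 0 of the others by camera at the preset correlation. Simulated genes were drawn independently, whereas the correlation estimated within the complex I list was 0.828. The simulation therefore does not cover lists of correlated genes. Each gene also had the same spread in every group, so a greater spread in E3 at 10 h was not simulated. Intervals of read ratios are exact 95% intervals and, like the floor of 3 counts over a group used where a group had 0 reads, cover counting error only. Fisher's exact tests and correlations were computed with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1, and plots with matplotlib 3.10.9.

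Groups of 2 are too small for other splits of the samples, and do not show which library of a group deviates. For complex I at 10 h and erythromycin genes at 48 h, the weakest of the 4 pairs of single libraries was examined instead. The differences between replicates 1 and 2 correlated weakly between groups (r from -0.06 to 0.104 across genes, which are not independent replicates). Whether cultures with the same number were grown or sequenced together is not given, and the main test took them as unpaired.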

Results

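Transcripts were measured in Saccharopolyspora erythraea, the actinomycete that makes erythromycin, in strain E3, the parent, and in EA, an engineered strain labelled E3::atpAGD. The genes atpA, atpG and atpD encode the alpha, gamma and beta subunits of ATP synthase, and the series title names a perturbation of intracellular ATP. Both strains grew in modified minimal liquid medium and were harvested at 10 h, in early exponential phase, and at 48 h, when exponential growth ended and erythromycin synthesis began per the labels. There were 2 cultures per strain and time, 8 libraries in all. Reads counted to the 7168 CDS came to 32.3 and 28.3 M for E3 at 10 h and 25.8 and 27.3 M for E3 at 48 h. They came to 24.7 and 31.95 M for EA at 10 h and 28.4 and 28.5 M for EA at 48 h. A CDS had a median of 496 to 728 reads per library, and the 10 most abundant CDS took 7.51% to 11.7% of the reads. Across genes, the first principal component held 68.9% of the variance and separated the times, and the second held 22.1% and separated the strains. Replicates differed by a median absolute log2 difference of 0.27 in E3 at 10 h and of 0.10 to 0.16 in the other groups.

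The comparison of EA with E3 at 10 h covered early exponential growth. EA is labelled as carrying added atpAGD genes but also had almost no reads in 2 chromosomal regions, so a difference between the strains was not assigned to either. Every measured gene of complex I, the NADH dehydrogenase that passes electrons from NADH to the respiratory chain, was higher in EA, by a median log2 fold change of 1.17. A urease operon, a ferritin and a 2-methylisoborneol synthase rose with many genes of sugar uptake and fatty acid oxidation, while 9 genes of purine and pyrimidine synthesis fell. The chromosomal ATP synthase genes did not pass the test. Over the genome, 2400 of 7118 genes changed, 1331 higher and 1069 lower, and 801 of them changed at least 2-fold, 527 higher and 274 lower.

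By the size of the change, the highest of the genes the rule named in EA at 10 h came from a few neighbourhoods. SACE_3203, a nucleotide sugar dehydrogenase, rose from 1.87 ± 0.362 to 179 ± 19.3 CPM (SD, n = 2), a log2 fold change of 6.56 ± 0.20 (SE), and its neighbour SACE_3204, with an EF-hand domain, rose by 6.29 ± 0.23 on the log2 scale. The 2-methylisoborneol synthase SACE_3722, which makes a volatile terpenoid, rose by 5.29 ± 0.21, together with the methyltransferase SACE_3721 (5.44 ± 0.18) and the cyclic nucleotide-binding protein SACE_3723 (5.21 ± 0.22). The regulator SACE_1895 of the XRE family (5.85 ± 0.24), the cation acetate symporter SACE_6333 (5.19 ± 0.16) and the protease inhibitor SACE_6374 (5.18 ± 0.20) completed the highest group. Among the genes still read in EA, the NAD-dependent epimerase SACE_0813 had the lowest log2 fold change of the genes the rule named, -3.57 ± 0.14. The L-serine ammonia-lyase SACE_6377 (-3.06 ± 0.29) and gcvH (SACE_6378, -2.75 ± 0.23), which encodes a protein of the glycine cleavage system, lie side by side and both fell. The hydrolase SACE_7276 (-2.87 ± 0.13), the MFS transporter SACE_1907 (-2.69 ± 0.17) and SACE_1905, with an MDR9 domain (-2.45 ± 0.21), fell as well.

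Almost no reads in EA fell in 2 stretches of the chromosome, each with an integrase gene. The first, from 519500 to 529786, held 14 CDS with 29840 reads in the 4 E3 libraries and 12 in the 4 EA libraries. The second, from 7823725 to 7840440, held 28 CDS with 28502 and 16 reads. In the first, the NUDIX hydrolase at 528614 to 529156 had 6673 reads in E3 and 1 in EA at 10 h, a ratio of 6234 (95% interval 1119 to 246284), and 5260 against 2 at 48 h, a ratio of 2821 (780.5 to 23298). In the second, SACE_7007, with an HDIG domain, had 6184 against 2 reads at 10 h, a ratio of 2889 (799.4 to 23859), and 4038 against 2 at 48 h, a ratio of 2165 (599.1 to 17887). The flanking genes were read in both strains: SACE_0463 had 17142 reads in E3 and 15908 in EA, SACE_0477 103 and 105, SACE_7004 7913 and 7492, and SACE_7033 5882 and 5040.0. A single CDS elsewhere, SACE_5448 of unknown function, had 707 reads in E3 and 0 in EA. With 0 reads in EA its ratio has no point value, and the lower 95% bounds were 70.7-fold at 10 h and 123-fold at 48 h. A floor of 3 counts would give 87.5 and 152, which are set by the floor and are not measured ratios. The regions were found after the values were seen, and 0 CDS showed the opposite pattern, with at most 10 reads in E3 and at least 40 in EA.

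**Figure D1:**
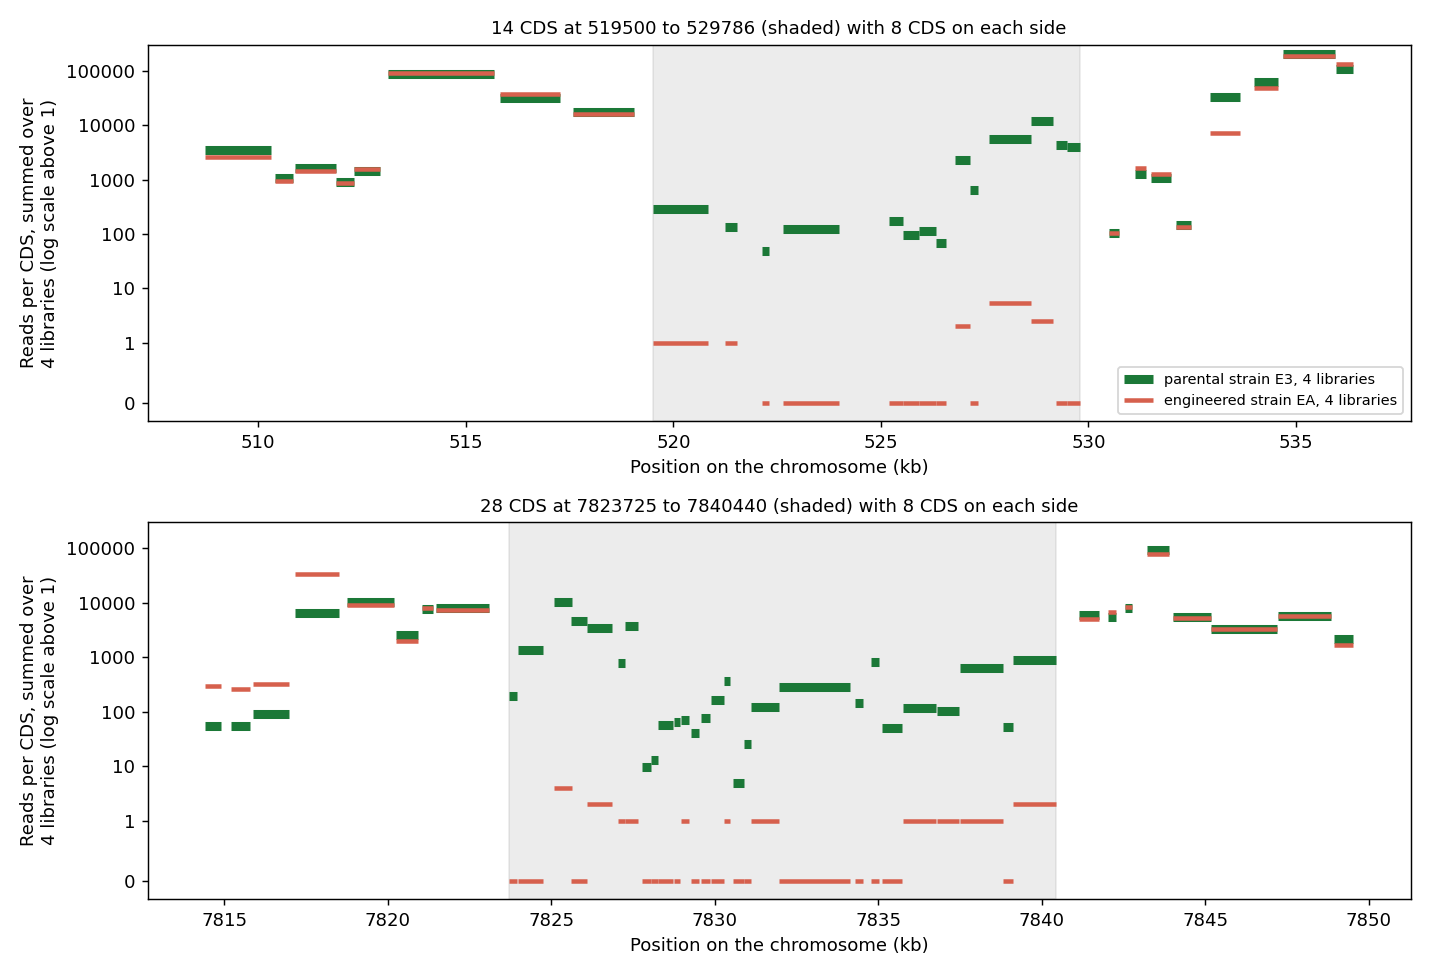
Reads of each CDS summed over the 4 libraries of a strain (log axis), by position on the chromosome in kb, for the 2 regions and their neighbours. E3 had 29840 and 28502 reads over the regions and EA had 12 and 16, while the flanking genes were read in both strains.

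Genes of energy metabolism at 10 h differed by complex. None of the 9 ATP synthase genes passed in edgeR: SACE_6282 (alpha subunit) had a log2 fold change of -0.12 ± 0.19, SACE_6281 (gamma) -0.15 ± 0.18 and atpD (SACE_6280, beta) -0.08 ± 0.20. At an unadjusted p under 0.05, 0 were higher and 1 was lower, SACE_6283 (delta, -0.36 ± 0.14, adjusted p = 0.0739). It was also the 1 member that DESeq2 called lower (adjusted p = 0.0338), and edgeR did without E3 10 h replicate 1 (0.0322). With library size alone as the scaling, SACE_6283 (0.0102), SACE_6284 (0.0346) and SACE_6285 (0.0253) passed as lower. The labels do not give the sequence of the added genes or the treatment of reads that fit several places. Whether reads of the added copies were counted on these genes is therefore open. In complex I, 14 of 14 members rose, also adjusted over the list alone (camera adjusted p = 4.6e-08; adjusted p = 0.662 with an estimated correlation). NuoI (SACE_6894) went from 63.8 ± 10.97 to 159 ± 1.67 CPM, a log2 fold change of 1.32 ± 0.14, and NuoF (SACE_6897) and NuoL (SACE_6891) had 1.28 ± 0.18 and 1.22 ± 0.14. In the rest of the respiratory chain, 5 of 27 members rose and 3 fell, also adjusted over the list alone, with a median of -0.00, a mean of 0.11 and a camera test that did not pass (adjusted p = 0.864). The risers were the cytochrome bd oxidase genes SACE_0142 (1.42) and cydB (SACE_0143, 1.93), the exporter gene cydD beside them (SACE_0144, 1.93), and the succinate dehydrogenase genes SACE_1170 (1.43) and SACE_1171 (1.19). The cytochrome c biogenesis gene SACE_0618 fell (-1.47).

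Central carbon genes at 10 h split within each pathway. In glycolysis and gluconeogenesis 1 of 14 members rose and 1 fell, also adjusted over the list alone, with a median of -0.02, a mean of -0.01 and a test direction upward (adjusted p = 0.954). Phosphoenolpyruvate carboxykinase (SACE_7274), a gluconeogenic enzyme, rose by 1.19. In the pentose phosphate pathway 2 of 15 rose and 4 fell, also adjusted over the list alone (median -0.26). The transketolases SACE_5763 (-2.12 ± 0.31), SACE_5762 (-1.71 ± 0.23) and SACE_4350 (-0.80) fell, and the ribose-5-phosphate isomerase SACE_5216 rose (1.06). In the TCA list 8 of 36 rose and 2 fell, also adjusted over the list alone (median 0.15). The largest change was in pdhA (SACE_2407, 1.82 ± 0.33), a subunit of pyruvate dehydrogenase. TCA members that rose numbered 19 without E3 10 h replicate 2 and 5 without EA 10 h replicate 1.

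Propionyl-CoA and methylmalonyl-CoA are the building blocks of the erythromycin ring. The list for their supply, which also holds acetyl-CoA carboxylase genes, had 5 of 14 members higher and 1 lower at 10 h. Adjusted over the list alone 6 were higher and 1 lower (median 0.30). An acetyl-CoA carboxylase biotin carrier subunit at 8165707 to 8165820 rose by 1.10. The higher members numbered 3 under library size alone, 2 with the 4 compared libraries fitted alone, 2 without E3 10 h replicate 1 and 1 without EA 10 h replicate 1. Degradation of branched-chain amino acids had 4 of 9 higher and 0 lower in edgeR, 5 and 0 adjusted over the list alone, with 0 lower also at an unadjusted p under 0.05 and in DESeq2 (median 0.55). Hydroxymethylglutaryl-CoA lyase (SACE_3041), of leucine breakdown, rose by 0.95.

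In fatty acid beta-oxidation 26 of 76 members rose and 4 fell at 10 h, 27 and 4 adjusted over the list alone (median 0.36; camera adjusted p = 0.00393; adjusted p = 0.662 with an estimated correlation). The acyl-CoA synthetase SACE_3216 (3.70 ± 0.14) and the acyl-CoA dehydrogenase SACE_5168 (2.02 ± 0.15) rose most. The 4 that fell were the hydratases SACE_3018 (-1.33), SACE_3450 (-0.85) and SACE_4571 (-1.01) and the ligase SACE_4038 (-1.15). In sugar uptake 17 of 56 rose and 3 fell, 18 and 3 adjusted over the list alone (median 0.49; camera adjusted p = 0.00249; adjusted p = 0.662 with an estimated correlation). SACE_1666 (1.27 ± 0.19) and SACE_1664 (1.18 ± 0.13) of an ABC transporter were higher. For beta-oxidation the members higher numbered 47 without E3 10 h replicate 2, 16 without EA 10 h replicate 1 and 14 without EA 10 h replicate 2. Under library size alone 10 sugar uptake genes were higher and 3 lower, and with the 4 libraries alone 11 and 2. They numbered 11 and 26 higher without E3 10 h replicate 1 and 2, and 9 without either EA 10 h replicate 1 or EA 10 h replicate 2.

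In nitrogen assimilation at 10 h, 11 of 38 members rose and 3 fell, 12 and 3 adjusted over the list alone (median 0.28; camera adjusted p = 0.0286; adjusted p = 0.662 with an estimated correlation). The risers included the urease genes SACE_2527 (gamma subunit, 5.12 ± 0.27), from 2.80 ± 1.43 to 94.7 ± 10.4 CPM, SACE_2526 (alpha subunit, 5.08 ± 0.33), ureG (SACE_2524, 4.04 ± 0.20) and SACE_2525 (2.85 ± 0.19). Urease splits urea into ammonia and carbon dioxide. The nitrate reductase SACE_3287 fell (-1.07). In purine and pyrimidine biosynthesis 9 of 29 fell, also adjusted over the list alone, and 0 rose in edgeR (0 also at an unadjusted p under 0.05 and in DESeq2; median -0.21; camera adjusted p = 0.00249; adjusted p = 0.662 with an estimated correlation). The 9 included pyrF (SACE_2084, -0.69 ± 0.13) and the IMP dehydrogenase-related SACE_6707 (-0.74 ± 0.13). With library size alone 14 of the list were lower, and with the 4 libraries alone 5. Of 59 measured ribosomal protein genes 1 fell in edgeR and 0 rose, and 0 passed adjusted over the list alone (median -0.08); at an unadjusted p under 0.05, and in DESeq2, 2 were lower and 0 higher. Among 34 translation factors and aminoacyl-tRNA synthetases 2 rose and 2 fell, with 0 adjusted over the list alone (2 higher and 4 lower at an unadjusted p under 0.05; 1 and 3 in DESeq2; median -0.19; camera adjusted p = 0.04; adjusted p = 0.789 with an estimated correlation). In the phosphate response 2 of 15 rose and 1 fell, also adjusted over the list alone, with a median of -0.02 and a mean of 0.03. The alkaline phosphatases SACE_2998 (1.14) and SACE_0175 (0.93) were higher. Without E3 10 h replicate 2, 22 members of the nitrogen list were higher, and without EA 10 h replicate 1, 2 members of the purine and pyrimidine list were lower.

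Few genes of the erythromycin cluster passed at 10 h. At an unadjusted p under 0.05, 8 of 21 measured members were higher and 1 lower. Adjusted over all genes 4 rose and 1 fell, against 2 and 1 adjusted over the list alone and in DESeq2. The median was 0.36, and camera pointed upward without passing (adjusted p = 0.0501). The risers were the methyltransferase SACE_0728 (0.59), the desosaminyl transferase gene eryCIII (SACE_0726, 0.56), the epimerase SACE_0714 (0.48) and the cytochrome P450 SACE_0725 (0.44). The gene that fell was SACE_0733, for the ErmE methyltransferase that protects the ribosome from erythromycin (-0.57). All 5 calls depended on single libraries. Without E3 10 h replicate 1, calls ended for SACE_0728 (0.0598), eryCIII (0.122), SACE_0714 (0.225) and SACE_0725 (0.218). Without E3 48 h replicate 1, calls ended for SACE_0714 (0.0683) and SACE_0725 (0.0714). Without E3 48 h replicate 2, calls ended for SACE_0714 (0.0685) and SACE_0725 (0.0715). Without EA 10 h replicate 1, calls ended for SACE_0714 (0.175) and SACE_0733 (0.0610). Without EA 10 h replicate 2, calls ended for SACE_0728 (0.105), eryCIII (0.203), SACE_0714 (0.111) and SACE_0725 (0.283). Without EA 48 h replicate 1, calls ended for SACE_0728 (0.0536), eryCIII (0.0515), SACE_0714 (0.0715) and SACE_0725 (0.0743). Without EA 48 h replicate 2, calls ended for SACE_0728 (0.0534), eryCIII (0.0513), SACE_0714 (0.0715) and SACE_0725 (0.0743). The 9 CDS of the cluster without a locus tag, 3 of them annotated polyketide synthase, were singled out after their values were seen. None passed in edgeR (0 in DESeq2), 2 were higher at an unadjusted p under 0.05, and the median was 0.11. In other secondary metabolism 11 of 38 rose and 9 fell, also adjusted over the list alone, with a median of -0.17 and a mean of 0.25. The terpene synthases SACE_3187 (4.00 ± 0.33) and SACE_3977 (3.73 ± 0.27) and the peptide synthetase SACE_1305 (3.35 ± 0.19) rose most.

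Stress and iron genes at 10 h were mixed. In the iron list 12 of 24 rose and 2 fell, 13 and 2 adjusted over the list alone (median 0.53; camera adjusted p = 0.0575). The ferritin SACE_4302, an iron store, rose by 5.05 ± 0.22, and the ferritin SACE_0130 fell (-1.03 ± 0.14). Of 42 oxidative stress genes 10 rose and 4 fell, also adjusted over the list alone (median 0.10). The mycothiol-dependent enzyme SACE_5315 was higher (1.15 ± 0.13), and the mycothiol synthesis gene mshB (SACE_1543) lower (-0.71). Under library size alone 5 oxidative stress genes were higher and 4 lower, and with the 4 libraries alone 5 and 2. Those higher numbered 5 and 16 without E3 10 h replicate 1 and 2, and 6 and 5 without EA 10 h replicate 1 and 2. Of 31 chaperones and proteases 3 rose and 6 fell, also adjusted over the list alone (median -0.07). The small heat shock protein SACE_0150 (-2.19 ± 0.23), the Clp ATPase SACE_3385 (-2.03 ± 0.20) and dnaK (SACE_5000, -1.09 ± 0.11) fell, and the small heat shock proteins SACE_2438 (3.05 ± 0.23) and SACE_3659 (1.03) rose.

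In development and sporulation at 10 h, 5 of 22 rose and 3 fell, also adjusted over the list alone, which turned to 2 and 3 under library size alone or with the 4 libraries alone, and to 4 and 4 under RLE or upper-quartile factors (median 0.13, mean -0.02). The SsgA-type regulator SACE_1961 rose (0.93), and the WhiB regulators SACE_5583 (-2.33 ± 0.20) and SACE_2853 (-0.99) fell. The higher members numbered 3 without E3 10 h replicate 1 or E3 48 h replicate 2, 1 without EA 10 h replicate 1 and 2 without EA 10 h replicate 2. Of 45 sigma and anti-sigma factors 10 rose and 7 fell, 11 and 7 adjusted over the list alone, against 5 and 7 under library size alone and 6 and 4 with the 4 libraries alone (median 0.11). SACE_1454, of the SigE family, rose (1.65 ± 0.20), and 6 were higher without EA 10 h replicate 1. In cell division and wall 2 of 27 rose and 6 fell, also adjusted over the list alone (median -0.17). The DivIVA-domain SACE_6104 rose (0.46). The lower members numbered 3 with the 4 libraries alone, 11 without E3 10 h replicate 2, 1 without EA 10 h replicate 1 and 2 without EA 10 h replicate 2.

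Of 161 measured mobile elements 5 rose and 26 fell at 10 h, 3 and 22 adjusted over the list alone (median -0.12; camera adjusted p = 0.0501). The transposases SACE_2536 (1.42) and CDS_3513280_3513393 (0.94) rose. The integrases of the regions without reads in EA were among those that fell. SACE_0464 had 157 reads in E3 and 1 in EA (ratio 147, interval 25.9 to 5830.1), and SACE_7032 had 424 and 2 (ratio 198, interval 54.5 to 1641). The lower members numbered 15 with the 4 libraries alone, and 15 and 14 without EA 10 h replicate 1 and 2.

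Further members made up the small counts of the lists at 10 h, and each lost its call with some single library left out. In energy and carbon metabolism these were the NADH dehydrogenase SACE_2433 (-1.89), the cytochrome biogenesis gene SACE_6932 (-0.42), pfkB (SACE_2273, -1.73), pgl (SACE_2155, -0.53), aceA (SACE_1449, -0.49) and acnA (SACE_3811, -0.55), all lower, and the isomerase SACE_4764 (0.46), higher. In the propionyl-CoA and methylmalonyl-CoA list they were the methylmalonyl-CoA mutase genes scpA (SACE_5639, 0.79) and SACE_5638 (0.54) and the epimerase mce (SACE_6238, 0.52). The acetyl-CoA carboxylase SACE_3856 (0.52) was higher too, and the acetyl-CoA carboxylase biotin carrier SACE_6428 was lower (-0.48). For valine breakdown they were mmsA (SACE_1456, 0.87), a second mmsA (SACE_4672, 0.56) and mmsB (SACE_1459, 0.55). The fructose transporter genes SACE_2274 (-1.46) and SACE_2275 (-1.52), the sugar-binding SACE_4778 (-0.31), the nitrate reductase genes narI (SACE_4067, -0.43) and narJ (SACE_4068, -0.50) and the exopolyphosphatase SACE_1948 (-0.42) were lower. In translation, rplI (SACE_7348, -0.40), alaS (SACE_2052, -0.41) and gltX (SACE_6148, -0.45) were lower, and EF-G2 (SACE_2008, 0.50) and the cysteinyl-tRNA ligase SACE_2667 (0.36) higher. In stress and iron, SACE_0187 (-0.43), a second mshB (SACE_1008, -0.57), the catalase gene katE (SACE_3861, -0.82) and the iron transporter SACE_0982 (-0.56) were lower and clpX (SACE_1362, 0.45) higher. In development and division, the WhiB genes SACE_6004 (1.73), SACE_6464 (0.47) and CDS_7520010_7520312 (0.38), the sigma factor whiG (SACE_6040, 0.36) and ftsZ (SACE_5835, 0.59) were higher and the WhiB gene SACE_1093 lower (-0.59). The transposases SACE_3366 (0.36), CDS_3313242_3313790 (1.42) and CDS_4064497_4065879 (0.84) were higher. Adjusted p values after each omission follow. Without E3 10 h replicate 1, calls ended for SACE_4764 (0.163), SACE_5638 (0.0568), mce (0.0562), SACE_3856 (0.0717), mmsA SACE_1456 (0.0512), mmsA SACE_4672 (0.203), mmsB (0.175), alaS (0.0669) and SACE_2008 (0.0800). That library also ended those of SACE_2667 (0.146), SACE_0982 (0.0766), clpX (0.135), CDS_7520010_7520312 (0.0581), whiG (0.0758), SACE_3366 (0.214) and CDS_4064497_4065879 (0.283). Without E3 10 h replicate 2, calls ended for aceA (0.133), rplI (0.0537) and SACE_0187 (0.105). Without E3 48 h replicate 1, calls ended for aceA (0.0543), acnA (0.0712), SACE_4764 (0.0576), mmsA SACE_4672 (0.0618), SACE_4778 (0.0743), rplI (0.0937), alaS (0.0681), SACE_2667 (0.0705) and SACE_0187 (0.0602). So did those of clpX (0.0607), CDS_7520010_7520312 (0.0559), SACE_3366 (0.0737) and CDS_4064497_4065879 (0.0760). Without E3 48 h replicate 2, calls ended for aceA (0.0544), acnA (0.0712), SACE_4764 (0.0567), mmsA SACE_4672 (0.0619), SACE_4778 (0.0749), rplI (0.0938), alaS (0.0682), SACE_2667 (0.0703) and SACE_0187 (0.0603). So did those of clpX (0.0607), CDS_7520010_7520312 (0.0560), whiG (0.0503), SACE_3366 (0.0733) and CDS_4064497_4065879 (0.0758). Without EA 10 h replicate 1, calls ended for SACE_6932 (0.0609), pgl (0.115), aceA (0.207), acnA (0.228), SACE_4764 (0.164), scpA (0.0505), SACE_5638 (0.110), mce (0.0668) and SACE_3856 (0.185). So did those of SACE_6428 (0.0974), mmsA SACE_1456 (0.0561), mmsA SACE_4672 (0.123), mmsB (0.179), SACE_2275 (0.0753), SACE_4778 (0.189), narI (0.0785), narJ (0.0619) and SACE_1948 (0.110). It also took those of rplI (0.243), alaS (0.182), gltX (0.123), SACE_2008 (0.0982), SACE_2667 (0.220), SACE_0187 (0.187), mshB SACE_1008 (0.0693), SACE_0982 (0.138) and clpX (0.0610). It also took those of SACE_6004 (0.0580), SACE_6464 (0.0524), CDS_7520010_7520312 (0.0683), whiG (0.0924), SACE_1093 (0.0790), SACE_3366 (0.144) and CDS_4064497_4065879 (0.111). Without EA 10 h replicate 2, calls ended for SACE_2433 (0.0572), SACE_6932 (0.0988), pfkB (0.0669), aceA (0.0875), SACE_4764 (0.0784), mce (0.0754), SACE_6428 (0.0840), mmsA SACE_1456 (0.0772) and mmsA SACE_4672 (0.160). So did those of mmsB (0.117), SACE_2274 (0.0552), SACE_2275 (0.0930), SACE_4778 (0.0977), narI (0.0582), narJ (0.0627), SACE_1948 (0.0926), rplI (0.0516) and alaS (0.0640). It also took those of SACE_2008 (0.0836), SACE_2667 (0.0587), SACE_0187 (0.0942), katE (0.131), SACE_0982 (0.113), clpX (0.147), SACE_6464 (0.0764), CDS_7520010_7520312 (0.119) and whiG (0.122). It also took those of ftsZ (0.0696), SACE_1093 (0.0930), SACE_3366 (0.141), CDS_3313242_3313790 (0.0667) and CDS_4064497_4065879 (0.175). Without EA 48 h replicate 1, calls ended for aceA (0.0571), acnA (0.0770), SACE_4764 (0.0596), mmsB (0.0619), SACE_4778 (0.0913), rplI (0.102), alaS (0.0727), SACE_2667 (0.0736) and SACE_0187 (0.0534). So did those of clpX (0.0662), whiG (0.0649), SACE_3366 (0.0854) and CDS_4064497_4065879 (0.0550). Without EA 48 h replicate 2, calls ended for aceA (0.0572), acnA (0.0770), SACE_4764 (0.0593), mmsB (0.0618), SACE_4778 (0.0922), rplI (0.102), alaS (0.0724), SACE_2667 (0.0734) and SACE_0187 (0.0536). So did those of clpX (0.0659), whiG (0.0650), SACE_3366 (0.0854) and CDS_4064497_4065879 (0.0561).

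In the whole comparison at 10 h, 1479 genes passed without EA 10 h replicate 1 and 1433 without EA 10 h replicate 2, against 2400 with all libraries. With the 4 compared libraries fitted alone 1610 passed. Of the genes changed in the main fit 55.5% were higher. That share was 49.6% under RLE, 49.4% in DESeq2, 48.4% under upper-quartile factors and 39.9% with library size alone. The excess of higher genes thus depended on the scaling. Library size alone moved the median of all genes to -0.16.

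**Figure D2:**
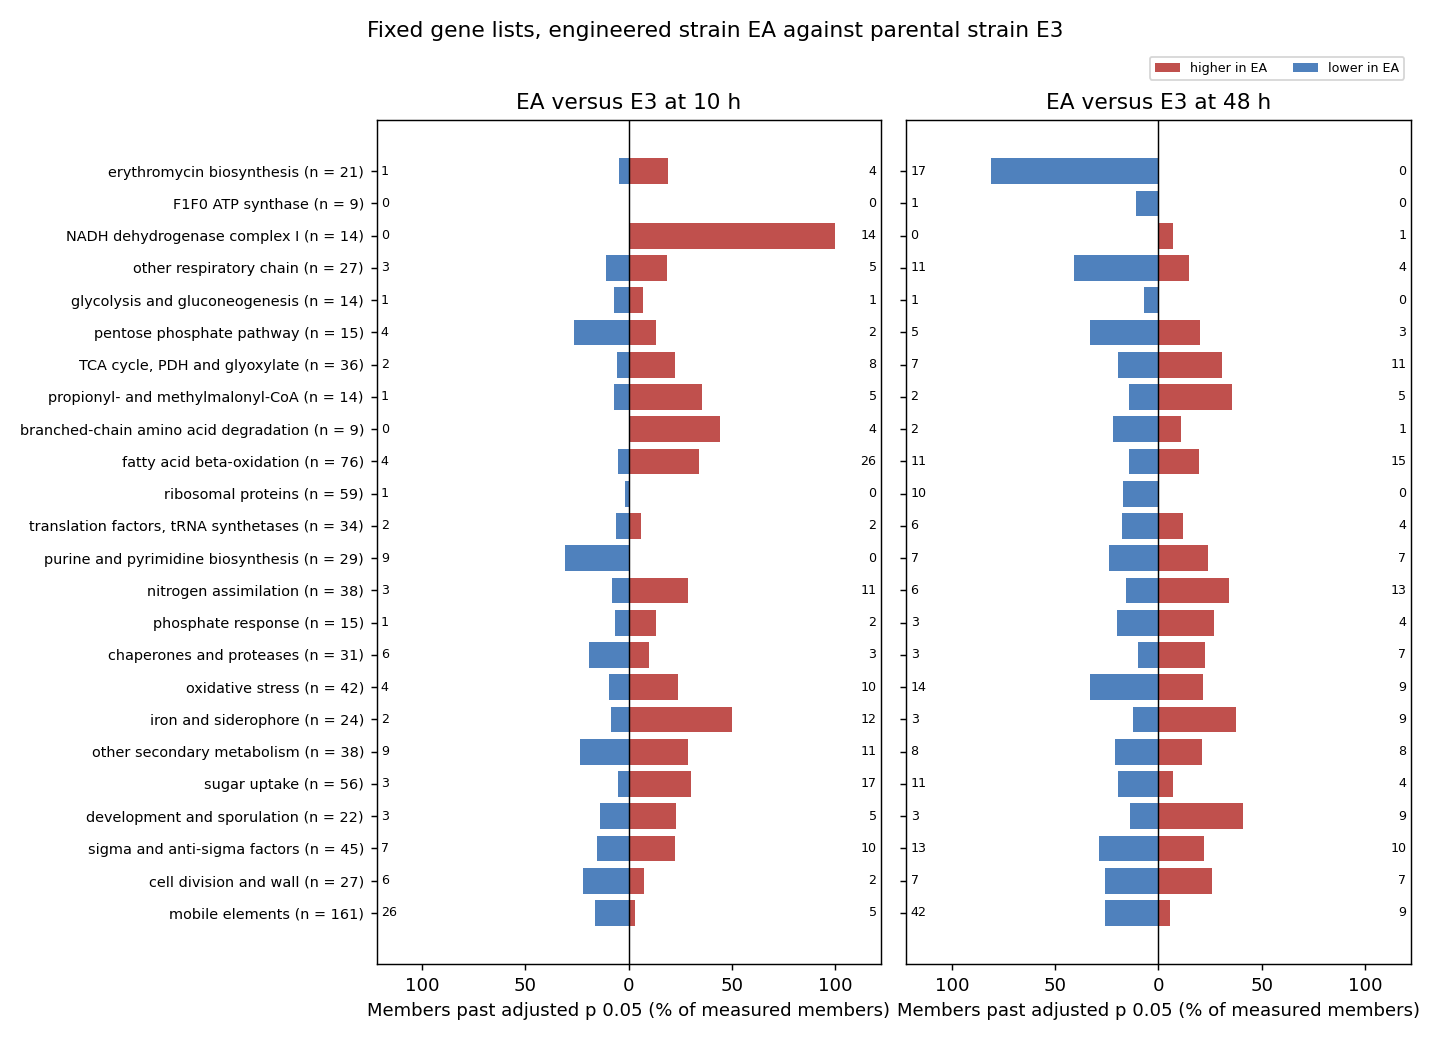
Share of measured members of each list that passed the test in EA against E3, at 10 h and at 48 h (% of members; higher to the right, lower to the left, with counts). All 14 complex I genes were higher at 10 h, and 17 of 21 erythromycin genes were lower at 48 h.

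The comparison at 48 h asked the same of the end of exponential growth, when erythromycin synthesis starts per the labels. The erythromycin cluster was lower in EA: 17 of its 21 measured members fell, also adjusted over the list alone, with a median log2 fold change of -0.76. Complex I had 1 of 14 members higher, and its strain difference was smaller than at 10 h (interaction camera adjusted p = 3.8e-06; adjusted p = 0.627 with an estimated correlation). The ATP synthase genes of the main operon did not pass. A WhiB regulator, a sigma factor, a ferritin and some urease genes were raised. A neighbourhood around SACE_4563 to SACE_4570 had the largest decreases among the genes the rule named that were still read in EA. In all, 3159 of 7118 genes changed, 1694 higher and 1465 lower, with 1146 at least 2-fold, 682 higher and 464 lower. With the 4 compared libraries fitted alone 4171 genes changed. Of the genes changed in the main fit 53.6% were higher. That share was 49.8% under RLE, 50.1% in DESeq2, 45.4% under upper-quartile factors and 42.8% with library size alone. The excess of higher genes thus depended on the scaling. Library size alone moved the median of all genes to -0.11.

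In the erythromycin cluster at 48 h the esterase SACE_0712 (-1.35 ± 0.25), the epimerase SACE_0714 (-1.004 ± 0.16), desII (SACE_0715, -0.99 ± 0.23) and the aminotransferase SACE_0716 (-0.96 ± 0.18) fell most. The last 3 act on sugars before these are attached to the macrolide. SACE_0714 went from 364 ± 19.9 CPM in E3 to 182 ± 5.66 in EA. No member rose in edgeR or in DESeq2 (0 also at an unadjusted p under 0.05), and the list passed camera (adjusted p = 2.7e-04; adjusted p = 0.929 with an estimated correlation). All 9 untagged CDS of the cluster fell too, also in DESeq2 (median -0.63). Without E3 48 h replicate 1 there were 11 lower members, without EA 48 h replicate 1 there were 9 and without EA 48 h replicate 2 there were 11. In other secondary metabolism 8 of 38 rose and 8 fell, 8 and 7 adjusted over the list alone. The type III polyketide synthase SACE_1243 rose (3.76 ± 0.14), while the polyketide genes SACE_4575 (-3.64 ± 0.20) and SACE_4574 (-3.53 ± 0.21) and the terpene synthase SACE_4907 (-1.997 ± 0.26) fell.

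Among ATP synthase genes at 48 h, SACE_6282 had -0.10 ± 0.19, SACE_6281 -0.06 ± 0.18 and atpD (SACE_6280) -0.05 ± 0.20, none past the threshold. The 1 member that fell was SACE_5295, annotated atpB and apart from the operon (-1.25 ± 0.18, adjusted p = 2.2e-04), also adjusted over the list alone, and 0 rose (0 also at an unadjusted p under 0.05 and in DESeq2). SACE_6285 (-0.32 ± 0.14, adjusted p = 0.0980) passed without E3 10 h replicate 1 (0.0331) or 2 (0.0359), under library size alone (0.0191) and upper-quartile factors (0.0484). Complex I had a median of 0.02. The 1 member that passed, nuoH (SACE_6895, 0.36, adjusted p = 0.0495), did not with DESeq2 (0.102). It also lost its call with 1 library left out (adjusted p = 0.0577 and 0.314 without E3 48 h replicate 1 or 2, 0.0744 and 0.0750 without EA 10 h replicate 1 or 2 and 0.198 and 0.138 without EA 48 h replicate 1 or 2). Adjusted over the list alone 0 passed. In the rest of the respiratory chain 4 of 27 rose and 11 fell, also adjusted over the list alone (median -0.34). Higher were ctaD (SACE_7041, 1.33 ± 0.12), a cytochrome c oxidase subunit, the NADH dehydrogenase SACE_2433 (1.02 ± 0.22), and the succinate dehydrogenase genes SACE_1170 (0.52; adjusted p = 0.121 without E3 48 h replicate 2 and 0.0695 and 0.0780 without EA 48 h replicate 1 or 2) and SACE_1171 (0.53; adjusted p = 0.196 and 0.0546 without E3 48 h replicate 1 or 2 and 0.0834 and 0.138 without EA 48 h replicate 1 or 2). The cytochrome c gene SACE_1685 (-0.93 ± 0.15) and the biogenesis gene SACE_0618 (-0.94 ± 0.19) were lower. In the TCA list 11 of 36 were higher and 7 lower (11 and 8 adjusted over the list alone), against 6 and 13 under library size alone and 7 and 9 under upper-quartile factors. The pyruvate dehydrogenase SACE_1218 rose (2.67 ± 0.16) and isocitrate lyase aceA (SACE_1449), of the glyoxylate bypass, fell (-1.25 ± 0.18). The TCA members higher came to 6, 6, 5 and 6 without E3 48 h replicate 1, E3 48 h replicate 2, EA 48 h replicate 1 and EA 48 h replicate 2. In the pentose phosphate pathway 3 of 15 members were higher at 48 h and 5 lower, also adjusted over the list alone (median -0.25). The transketolases SACE_5762 (1.17 ± 0.23) and SACE_5763 (1.30 ± 0.31) were among the higher. SACE_5763 lost its call without E3 48 h replicate 2 or without EA 48 h replicate 1.

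Single regulators were among the genes with the largest increases at 48 h, and the nitrogen and iron lists did not pass camera (adjusted p = 0.153 and 0.109). The WhiB family regulator at 7520010 to 7520312 went from 9.22 ± 0.142 to 1219.7 ± 78.8 CPM, a log2 fold change of 7.05 ± 0.14, and the WhiB gene SACE_6464 rose by 3.30 ± 0.13; this family controls development and antibiotic genes in actinomycetes. In development and sporulation 9 of 22 rose and 3 fell, 11 and 3 adjusted over the list alone (median 0.37). The 3 were the WhiB genes SACE_5583 (-1.52) and CDS_352835_353134 (-0.91) and SACE_6445 (-0.85). The sigma factor SACE_0234 rose by 4.73 ± 0.32 and the anti-sigma antagonist SACE_2813 fell (-2.24 ± 0.13). In nitrogen assimilation 13 of 38 rose and 6 fell, also adjusted over the list alone, against 20 and 8 with the 4 libraries alone (median 0.23). The ureases SACE_2527 (5.05 ± 0.27) and SACE_2526 (4.40 ± 0.32), the nitrate reductase SACE_3423 (2.01 ± 0.17) and the glutamine synthetase SACE_3095 (1.94 ± 0.18) were higher. The nitrate reductase subunit narI was lower (SACE_4067, -1.01 ± 0.11). Among iron genes 9 of 24 rose and 3 fell, also adjusted over the list alone (median 0.31). The ferritin SACE_4973 rose by 4.36 ± 0.32, and the ferritin SACE_0130 (-2.02 ± 0.14), the transporter SACE_5744 (-0.92) and the isochorismate synthase SACE_6911 (-0.58; adjusted p = 0.0766 without EA 48 h replicate 1) fell. Under library size alone 5 iron genes were higher and 3 lower. Without E3 10 h replicate 2 there were 14 higher and without E3 48 h replicate 1 there were 5. Of the genes the rule named, the first WhiB gene and those that follow had the largest increases. They were the protease inhibitors SACE_1398 (7.11 ± 0.21) and SACE_6374 (6.56 ± 0.21), the GGDEF protein SACE_7360 (6.65 ± 0.15) and SACE_1895 (6.73 ± 0.25). SACE_3764 (6.42 ± 0.23), the peptidase SACE_4026 (6.25 ± 0.19) and SACE_3204 (5.71 ± 0.23) completed them. Among the genes the rule named that were still read in EA, the largest decreases were in SACE_4563 (-4.84 ± 0.31), SACE_4565 (-4.70 ± 0.25) and SACE_4564 (-4.59 ± 0.26). Next came the 3-oxoacyl-ACP synthase SACE_4567 (-4.49 ± 0.26), the acyl carrier protein SACE_4568 (-4.39 ± 0.24) and the hydroxymethylglutaryl-CoA synthase SACE_4570 (-4.36 ± 0.21). A sugar ABC transporter also fell, with SACE_5840 at -2.24 ± 0.30, SACE_5841 at -2.14 ± 0.20 and SACE_5839 at -1.76 ± 0.30.

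The strain differences at the 2 times overlapped. Of the genes higher in EA at 10 h, 628 were also higher at 48 h, where 317 would be shared by chance, and 440 were lower at both times, against 220.0 by chance. Opposite calls were fewer than chance, 155 and 144 against 274 and 254. Across genes, which are not independent replicates, the log2 fold changes at the 2 times had a Pearson r of 0.641, and of 0.452 without the CDS unread in EA. The 2 comparisons contrast different libraries. Their tests share an estimate of the spread over all 8 libraries, so the 2 sets of calls are not independent.

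**Figure D3:**
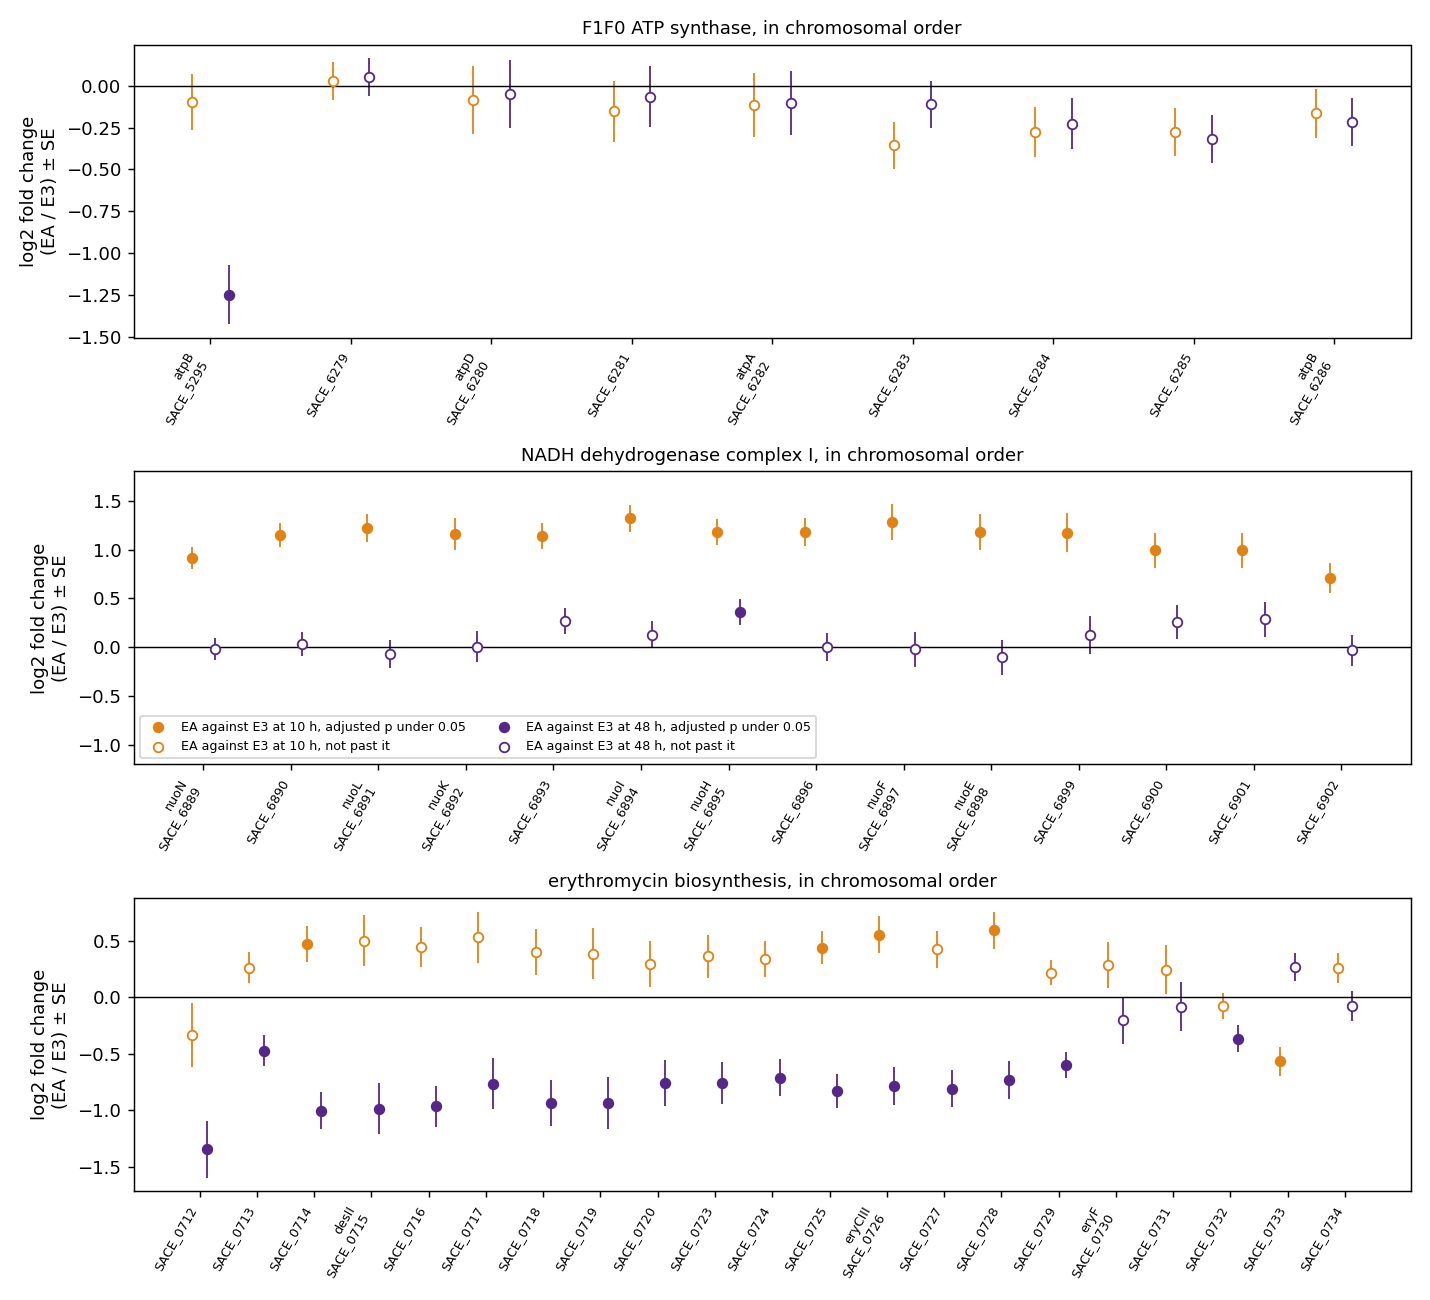
Log2 fold change of EA against E3, with SE, of each gene of ATP synthase, complex I and the erythromycin cluster in chromosomal order. Both 10 h and 48 h are drawn, and filled points passed at an adjusted p under 0.05. All 14 complex I genes were higher in EA at 10 h.

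The comparison of 48 h with 10 h in E3 showed the change with growth phase in the parental strain. Genes for nitrate and nitrite use were among those that rose most, by more than 9 on the log2 scale, while ribosomal proteins, ATP synthase and 3 chaperonin genes fell. The erythromycin cluster had 1 of 21 members higher and 6 lower, but 12 higher and 5 lower under library size alone and 5 of each under upper-quartile factors, so its direction depended on the scaling. In all, 5200 of 7118 genes changed, 2622 higher and 2578 lower, with 3089 at least 2-fold, 1665 higher and 1424 lower. Library size alone moved the median of all genes from 0.04 to 0.39 and upper-quartile factors to 0.16, and with library size alone 65.4% of the changed genes were higher, against 50.4%.

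Nitrogen assimilation had 28 of 38 members higher and 5 lower in E3 at 48 h, 29 and 5 adjusted over the list alone (median 1.59; camera adjusted p = 4.3e-06; adjusted p = 0.453 with an estimated correlation). The nitrite reductase genes nirB (SACE_3802, 9.47 ± 0.39) and nirD (SACE_3803, 9.39 ± 0.32), the nitrate transporter SACE_3799 (9.35 ± 0.31), the molybdopterin oxidoreductase SACE_3800 (9.65 ± 0.35), SACE_3801 (9.59 ± 0.33) and SACE_3804 (9.55 ± 0.36) lie side by side. NirB (SACE_3802) went from 10.9 ± 5.68 to 7657 ± 31.9 CPM. The urease gene ureA (SACE_3484) rose by 5.39 ± 0.17. The genes of ammonium assimilation glnA (SACE_1613, -1.70 ± 0.14), gltD (SACE_3997, -2.43 ± 0.16), gltB (SACE_3998, -1.42 ± 0.21), a second gltD (SACE_5741, -0.94 ± 0.15) and gdhA (SACE_5979, -1.58 ± 0.14) were the 5 that fell. The lytic transglycosylase SACE_2472 (9.40 ± 0.29) and the acetyltransferase SACE_5214 (9.32 ± 0.37) were among the genes that rose most.

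In E3 at 48 h, of 59 ribosomal protein genes 53 fell and 2 rose, also adjusted over the list alone (median -1.51; camera adjusted p = 1.8e-09; adjusted p = 0.649 with an estimated correlation), with rplJ (SACE_6868) at -2.26 ± 0.18. The 2 were rplU (SACE_1414, adjusted p = 0.151 and 0.0915 without E3 48 h replicate 1 or 2 and 0.0686 and 0.0685 without EA 48 h replicate 1 or 2) and rpmG (SACE_6877, adjusted p = 0.0570 without E3 48 h replicate 1). Translation factors and synthetases had 25 of 34 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 4.7e-04; adjusted p = 0.649 with an estimated correlation), including tsf (SACE_6037, -2.17 ± 0.16) and tuf (SACE_6838, -1.77 ± 0.18). The ligases cysS (SACE_0443, 0.37; adjusted p = 0.0934 without E3 48 h replicate 2) and trpS (SACE_1002, 0.41) were the higher pair. TrpS (SACE_1002) lost its call more widely (adjusted p = 0.217 without E3 10 h replicate 1, 0.0501 and 0.185 without E3 48 h replicate 1 or 2, 0.0546 and 0.0543 without EA 10 h replicate 1 or 2 and 0.0507 and 0.0506 without EA 48 h replicate 1 or 2). All 9 ATP synthase genes fell, also adjusted over the list alone (median -2.07; camera adjusted p = 4.9e-04; adjusted p = 0.649 with an estimated correlation): SACE_6282 by -2.25 ± 0.20, SACE_6281 -1.89 ± 0.19, atpD (SACE_6280) -2.07 ± 0.21 and SACE_6284 -2.89 ± 0.16. The smallest, SACE_5295 (-0.41 ± 0.17, adjusted p = 0.0441), lost its call in DESeq2 (0.0592). It also did with 1 library left out (adjusted p = 0.236 without E3 10 h replicate 1, 0.0848 and 0.202 without E3 48 h replicate 1 or 2, 0.0572 and 0.0576 without EA 10 h replicate 1 or 2 and 0.0638 and 0.0644 without EA 48 h replicate 1 or 2). Purine and pyrimidine biosynthesis had 17 of 29 lower and 4 higher, also adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.712 with an estimated correlation), with pyrF (SACE_2084) at -1.97 ± 0.13. The 4 that rose were purU (SACE_4502), guaA (SACE_6701), purF (SACE_7125) and SACE_4696 (adjusted p = 0.118 without E3 10 h replicate 1 and 0.113 and 0.0669 without E3 48 h replicate 1 or 2). Chaperones and proteases had 19 of 31 lower and 6 higher, 20 and 6 adjusted over the list alone (camera adjusted p = 0.0302; adjusted p = 0.453 with an estimated correlation). The chaperonin genes groL (SACE_0527, -4.97 ± 0.31), groES (SACE_6715, -4.12 ± 0.23) and a second groL (SACE_6714, -3.26 ± 0.29) fell. Methionine synthase metE (SACE_4744, -5.51 ± 0.39), argininosuccinate synthase argG (SACE_2917, -4.86 ± 0.15), ribonucleotide reductase SACE_1282 (-4.93 ± 0.31), the glycoside hydrolase SACE_2277 (-5.42 ± 0.50) and the transporters SACE_2830 (-5.09 ± 0.23) and SACE_4121 (-4.81 ± 0.18) also had large decreases.

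Other groups in E3 were divided. The nickel superoxide dismutase gene sodN (SACE_6419) fell from 6039 ± 515 to 32.01 ± 3.82 CPM (-7.56 ± 0.22), while the superoxide dismutases SACE_0619 (4.83 ± 0.16) and SACE_5364 (3.69 ± 0.12) and the thioredoxin SACE_2469 (7.99 ± 0.24) rose. Isocitrate lyase aceA (SACE_1449, -3.33 ± 0.18) and the succinate-CoA ligase genes SACE_6669 (-2.76 ± 0.22) and SACE_6668 (-2.70 ± 0.23) fell, and phosphoenolpyruvate carboxykinase (SACE_7274, 2.71 ± 0.21) rose. In the erythromycin cluster the beta-glucosidase SACE_0732 (-1.98 ± 0.12), eryF (SACE_0730, -1.38 ± 0.21), which hydroxylates the macrolide ring, and SACE_0731 (-1.34 ± 0.22) fell. The esterase SACE_0712 rose (1.19 ± 0.25), as did all 9 untagged CDS (median 0.83). Adjusted over the list alone 1 member was higher and 5 lower, and without E3 10 h replicate 1 there were 10 lower members. Mobile elements had 71 of 161 higher and 25 lower, 67 and 24 adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.453 with an estimated correlation), with the transposase SACE_2333 at 6.97 ± 0.24.

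**Figure D4:**
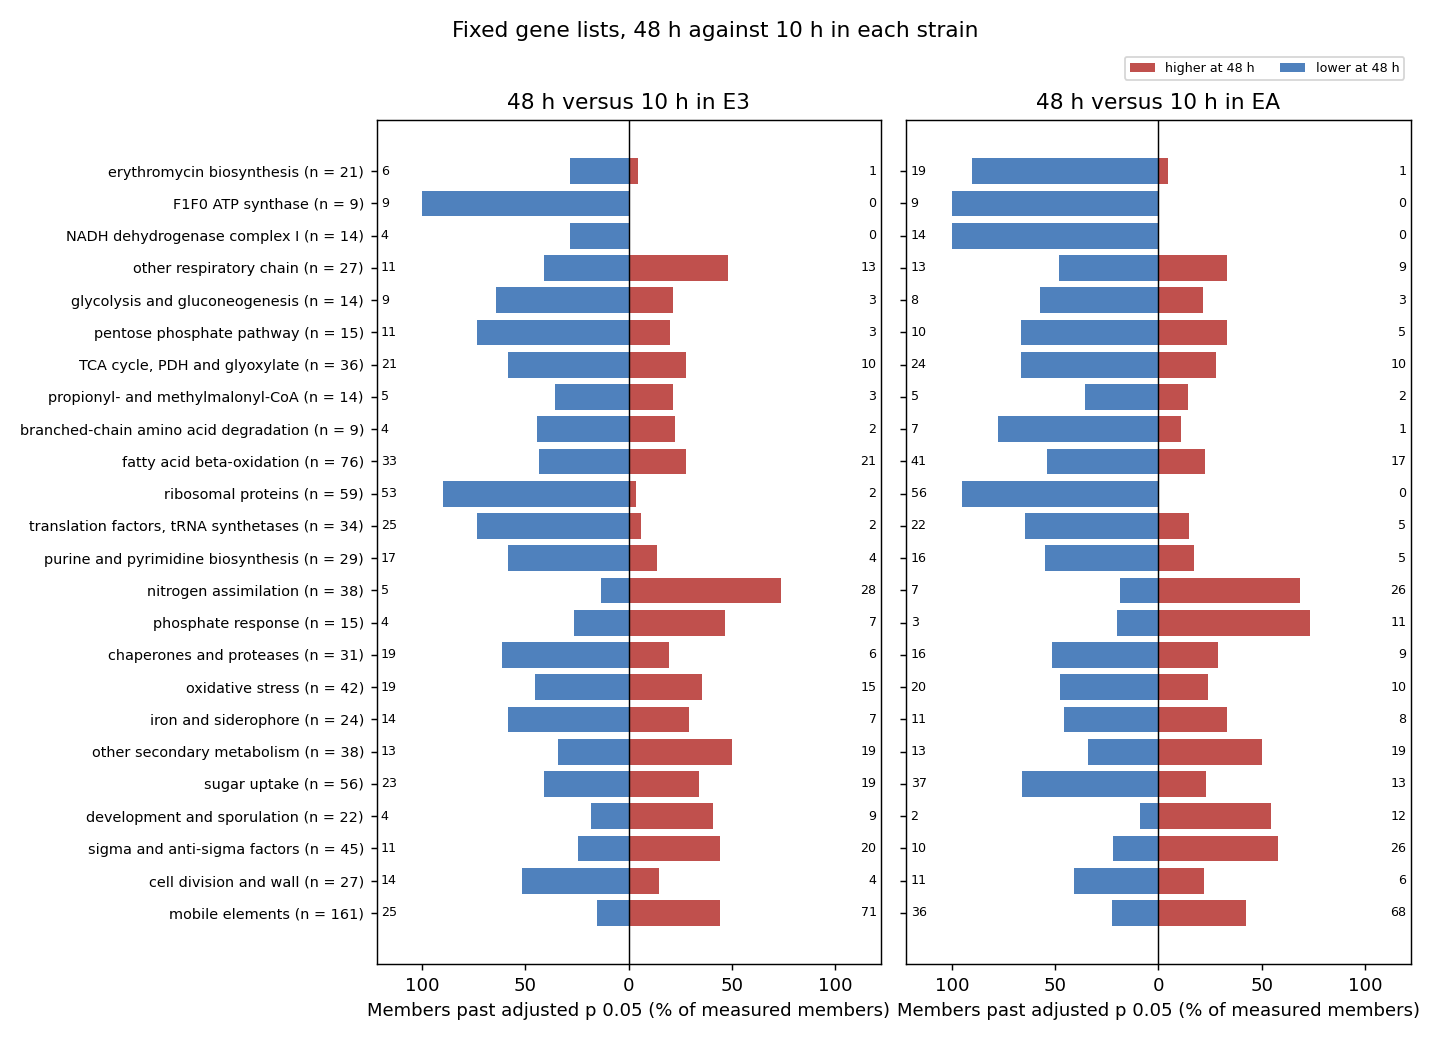
Share of measured members of each list that passed the test at 48 h against 10 h, in E3 and in EA (% of members; higher to the right, lower to the left, with counts). Ribosomal proteins had 53 of 59 lower in E3 and 56 in EA, and complex I had 14 of 14 lower in EA.

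In EA the change from 10 h to 48 h shared most calls with E3, with more complex I, erythromycin and sugar uptake genes lower. In E3 these were 4 of 14, 6 of 21 and 23 of 56, with 0, 1 and 19 higher. Of 7118 genes 5393 changed, 2717 higher and 2676 lower, with 3365 at least 2-fold, 1814 higher and 1551 lower. In detail, 2066 were higher in both strains (1001 by chance) and 2091 lower in both (969 by chance), and the fold changes had a Pearson r of 0.828 across genes. With library size alone 65.0% of the changed genes were higher, against 50.4%, and the median of all genes moved to 0.43, against 0.11 with upper-quartile factors. Complex I, which did not pass camera in E3 (adjusted p = 0.314), fell in 14 of 14 members (median -1.28; camera adjusted p = 2.5e-04; adjusted p = 0.494 with an estimated correlation). The erythromycin cluster had 19 of 21 lower and 1 higher (median -1.26; camera adjusted p = 3.4e-04; adjusted p = 0.494 with an estimated correlation), both lists also adjusted over the list alone. The 9 untagged CDS of the cluster did not fall as a group (median -0.01). CDS_788307_789215 (0.66) and CDS_797130_797804 (0.29; adjusted p = 0.0742 and 0.0732 without E3 48 h replicate 1 or 2, 0.242 without EA 10 h replicate 2 and 0.165 and 0.168 without EA 48 h replicate 1 or 2) rose. CDS_791232_792158, annotated polyketide synthase, fell (-0.41). It lost its call without either replicate of E3 at 48 h, of EA at 10 h or of EA at 48 h. ErmE (SACE_0733) was the 1 listed member that rose (1.048 ± 0.13). The difference from E3 passed for complex I (interaction camera adjusted p = 3.8e-06; adjusted p = 0.627 with an estimated correlation) and for the cluster (5.1e-06; adjusted p = 0.627 with an estimated correlation). Sugar uptake had 37 of 56 lower and 13 higher (camera adjusted p = 0.00512; adjusted p = 0.494 with an estimated correlation) and beta-oxidation 41 of 76 lower and 17 higher (0.0275; adjusted p = 0.63 with an estimated correlation). Development had 12 of 22 higher and 2 lower (camera adjusted p = 0.0239; adjusted p = 0.494 with an estimated correlation), all also adjusted over the list alone. The lower pair was bldD (SACE_2077) and whiG (SACE_6040). As in E3, ribosomal proteins (56 of 59 lower; camera adjusted p = 1.2e-09; adjusted p = 0.494 with an estimated correlation) and ATP synthase (9 of 9 lower; camera adjusted p = 3.4e-04; adjusted p = 0.494 with an estimated correlation) fell. Nitrogen assimilation had 26 of 38 higher and 7 lower, 27 and 7 adjusted over the list alone (camera adjusted p = 2.5e-04; adjusted p = 0.494 with an estimated correlation). Of the genes the rule named, SACE_5214 (10.41 ± 0.39), SACE_3804 (10.08 ± 0.37), SACE_3805 (10.02 ± 0.30) and SACE_3800 (9.91 ± 0.35) rose most. Those that fell most were sodN (SACE_6419, -7.53 ± 0.22), SACE_4567 (-6.93 ± 0.28), the lantipeptide gene SACE_4231 (-6.59 ± 0.27) and SACE_4563 (-6.54 ± 0.33). ATP synthase SACE_6282, SACE_6281 and atpD (SACE_6280) had -2.23 ± 0.20, -1.81 ± 0.19 and -2.03 ± 0.21.

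The interaction tested whether the strain difference itself changed between 10 h and 48 h. Complex I had 13 of 14 members with a lower strain difference at 48 h than at 10 h, 14 adjusted over the list alone, with a median of -1.08 (camera adjusted p = 3.8e-06; adjusted p = 0.627 with an estimated correlation). NuoF (SACE_6897) had -1.30 ± 0.26. The erythromycin cluster had 15 of 21 lower and 1 higher, 16 and 1 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 5.1e-06; adjusted p = 0.627 with an estimated correlation). DesII (SACE_0715) was at -1.49 ± 0.32, SACE_0714 at -1.48 ± 0.23 and ermE (SACE_0733), the 1 higher, at 0.84 ± 0.18. Of the 9 untagged CDS 8 were lower. Sugar uptake had 15 of 56 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.627 with an estimated correlation), with SACE_5840 at -2.89 ± 0.43 and ptsP (SACE_7368), the 1 higher, at 0.48. Its call ended with 1 library left out (adjusted p = 0.180 and 0.0622 without E3 48 h replicate 1 or 2, 0.0951 and 0.10003 without EA 10 h replicate 1 or 2 and 0.105 and 0.147 without EA 48 h replicate 1 or 2). The rest of the respiratory chain had 9 of 27 lower and 2 higher, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0195; adjusted p = 0.627 with an estimated correlation). CydB (SACE_0143) was at -2.31 ± 0.20, and SACE_2433 (2.91) and ctaD (SACE_7041, 1.22) were higher. Purine and pyrimidine biosynthesis had 9 of 29 higher and 0 lower in edgeR, also adjusted over the list alone (1 lower at an unadjusted p under 0.05 and 0 in DESeq2; camera adjusted p = 0.154). Among them pyrF (SACE_2084) was at 1.498 ± 0.18 and pyrC (SACE_2080) at 1.35 ± 0.26. Among ATP synthase genes 1 passed, SACE_5295 (-1.15 ± 0.24), and SACE_6282, SACE_6281 and atpD (SACE_6280) had 0.01 ± 0.27, 0.09 ± 0.26 and 0.04 ± 0.29. Of the genes the rule named, the largest interaction was in the WhiB CDS at 7520010 to 7520312 (6.66 ± 0.17) and the peptidase SACE_4026 (5.51 ± 0.37). Next came SACE_6132 (4.82 ± 0.36) and pdxS (SACE_2009, 4.71 ± 0.41), which makes the cofactor pyridoxal phosphate. At the other end were the deaminase SACE_1260 (-5.39 ± 0.56), SACE_4231 (-5.14 ± 0.32), pucD (SACE_1261, -4.99 ± 0.47) and SACE_1262 (-4.96 ± 0.47), of purine degradation. Over the genome 2189 of 7118 genes passed, 1080 higher and 1109 lower, with 1252 at least 2-fold, 609 higher and 643 lower, and 1448 passed without E3 48 h replicate 1.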

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

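The tests of scaling and of a steady change with time in this part were chosen after the results were seen, whereas those of a single deviating library and of the neighbouring genes were set before the values they measure. A test of the difference between the strain effects at 10 h and 48 h singled out 2189 genes and, at the preset correlation, 4 gene lists. None of the 4 passed with an estimated correlation (adjusted p = 0.627). By median difference these lists were erythromycin biosynthesis (-1.12), complex I (-1.08), sugar uptake (-0.58) and the rest of the respiratory chain (-0.42). It also singled out 8 genes named for the size of their difference. The WhiB regulator at 7520010 to 7520312 (6.66), the peptidase SACE_4026 (5.51), the oxidase family protein SACE_6132 (4.82) and pdxS (SACE_2009, 4.71) gained in EA relative to E3 by 48 h. The deaminase SACE_1260 (-5.39), the lantipeptide gene SACE_4231 (-5.14), pucD (SACE_1261, -4.99) and the 8-oxoguanine deaminase SACE_1262 (-4.96) lost.

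Complex I genes, which pass electrons from NADH to the respiratory chain, were higher in EA at 10 h in 14 of 14 members, and stayed at 14 under each of 3 other scalings, which argues against scaling. A single deviating library was argued against by the weakest of the 4 pairs of single libraries, with a median log2 ratio of 0.95 (95% bounds 0.67 to 1.02). Bounds here and in the next paragraph are taken over genes, which lie close together and are not independent. They do not measure the spread between cultures. If EA were further along a steady course from 10 h to 48 h, the genes would climb with time in E3, but their median change there was -0.14 (bounds -0.47 to -0.09). A transient peak between the sampled times stays open. As a hypothesis, the difference belongs to the strain, and what in EA brings it was not tested.

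Erythromycin genes, for the antibiotic and its sugars, were lower in EA at 48 h in 17 of 21 members, and stayed at 17 under each of 3 other scalings. With RLE, upper-quartile factors and library size alone, the median of all genes at 48 h moved to -0.03, -0.07 and -0.11, from 0.01. Each shift makes a lower call easier, so this test could not argue against scaling. The weakest of the 4 pairs of single libraries had a median of -0.73 (bounds -0.85 to -0.45), which argues against a single deviating library. The 20 CDS on each side of the cluster had a median of -0.31 (bounds -0.80 to -0.07), so a decrease of a wider stretch of the chromosome cannot be told apart, since the bounds include the size it needs. An effect of the strain at the onset of synthesis stays open beside it, untested.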

How the results depend on the processing

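Library size alone, upper-quartile factors, and the fits without CDS lacking a locus tag or CDS silent in EA were added after the data were seen. Among the gene values followed 1 reversed, that of the transposase CDS_82841_83683 with time in EA (0.0892 with library size alone against -0.30). In some lists the order of the counts of members higher and lower also turned with the scaling. With library size alone, erythromycin genes with time in E3 went from 1 higher and 6 lower to 12 and 5, the TCA list at 48 h from 11 and 7 to 6 and 13, and purine and pyrimidine genes with time in EA from 5 and 16 to 10 and 6. With an absolute log2 fold change of at least 1, changed genes came to 801 at 10 h, 1146 at 48 h, 3089 with time in E3, 3365 with time in EA and 1252 for the interaction, against 2400, 3159, 5200, 5393 and 2189. With 1 library left out they ranged from 1433 (without EA 10 h replicate 2) to 3541 (without E3 10 h replicate 2) at 10 h, and also fell to 1479 without EA 10 h replicate 1. They ranged from 2109 to 3978 at 48 h, 4501 to 5268 in E3, 4820.0 to 5746 in EA, and 1448 (without E3 48 h replicate 1) to 3186 (without E3 10 h replicate 2) for the interaction. A group left with 1 library is assumed to vary like the others. DESeq2 gave 2413, 3117, 5066, 5320.0 and 2210.0, and the replicate number as a block 2343, 3127, 5145, 5370.0 and 2140.0. The 4 compared libraries fitted alone gave fewer at 10 h, 1610, and more at 48 h, 4171. They gave 4829 with time in E3 and 5711 with time in EA. Replicates with the same number deviated together little (correlations of -0.06 to 0.10 between groups), and whether the number is a pairing is unknown. Of the gene values followed, 709 of which were past the threshold, calls were lost or gained in 22 and 1 with DESeq2, 17 and 0 with RLE, 18 and 0 with the block, 46 and 2 with the 4 libraries compared alone, 48 and 4 with library size alone and 20 and 1 with upper-quartile factors. With 1 library left out, 505 such values lost their call, 3 gained one and 5364 did neither. Of 120 list tests 28 passed, and 0 did with an estimated correlation (smallest adjusted p = 0.453). Lists whose estimated correlation was under the preset 0.01 lost their call too. For chaperones and proteases with time in E3 it was 0.001, and the camera adjusted p went from 0.0302 to 0.453. For development and sporulation with time in EA it was -0.02, and the camera adjusted p went from 0.0239 to 0.494. A correlation above the preset therefore does not account for every loss. With the replicate number as a block, 2 list tests that had not passed did so. Counts of list members moved by more than 1.5 times in 20 of 97 with library size alone, in 14 with the 4 libraries compared alone, against 67 that did not, and in 107 with 1 library left out, against 669 that did not. The causes were not tested.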

Other observations

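The runs of neighbouring genes, the stress protein group, the position trend and all tests of the silent regions in this part were chosen after the values were seen. Beyond the lists, changed genes came in runs of at least 5 neighbouring CDS that changed the same way by at least 2-fold. At 10 h EA had 16 such runs higher, with 123 CDS, and 5 lower, with 47, and at 48 h 18 higher, with 124, and 17 lower, with 143. SACE_3198 to SACE_3220, 23 CDS that include the sugar dehydrogenase SACE_3203, had a median log2 fold change of 3.85 at 10 h. SACE_3971 to SACE_3981, 11 CDS with a terpene synthase, had 2.82, SACE_4298 to SACE_4305, 8 CDS around the ferritin SACE_4302, had 4.29, and SACE_6331 to SACE_6338, 7 CDS with an acetate symporter, had 4.22 at 10 h and 3.94 at 48 h. At 48 h, SACE_4331 to SACE_4336, 6 CDS with amidinotransferases, were higher by a median of 4.75 and SACE_3058 to SACE_3064, 6 CDS with hydrogenase genes, by 2.46. Lower at 48 h were SACE_4559 to SACE_4577, 19 CDS with polyketide genes, by a median of -4.23, SACE_4644 to SACE_4652, 9 CDS with prenyltransferases, by -2.19, and SACE_4678 to SACE_4687, 10 CDS with biotin synthesis genes, by -2.13. A purine degradation run turned around: SACE_1259 to SACE_1264 had 1.34 at 10 h and SACE_1258 to SACE_1264 had -3.48 at 48 h, and in E3 the latter went up by 4.48 with time.

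With growth phase, E3 had 75 runs higher, with 633 CDS, and 52 lower, with 377. They included rhamnose use (SACE_4100 to SACE_4106, 8 CDS, 5.09) among the higher and phenylacetate breakdown (SACE_3542 to SACE_3548, 7 CDS, -3.39) and the methionine cycle (SACE_3895 to SACE_3901, 7 CDS, -3.72) among the lower. A stretch of 106 CDS, SACE_2400 to SACE_2507, had 98 higher and 3 lower in E3 and 102 higher in EA, with medians of 2.34 and 2.78, and held 18 of the 29 universal stress protein genes. Of these 29, 24 were higher in E3 (Fisher exact two-sided p = 5.0e-07) and 24 in EA (1.9e-06), but of the 11 outside the stretch 6 were higher in E3 (p = 0.229). CDS were also put in 8 bins by distance from the nearer end of the chromosome coordinates, with both arms pooled. The median change in E3 was -0.19 in the nearest, -0.37, -0.35, -0.13 and -0.11 in bins 2 to 5, and 0.79, 0.67 and 0.45 in bins 6 to 8. This was a step and not a steady rise (Spearman rho across genes 0.247, and 0.209 in EA). Bin 6 holds the stretch SACE_2400 to SACE_2507.

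The 2 regions with almost no reads in EA each hold an integrase gene and have neighbours that were read in both strains. Lower depth is argued against, since 58272 reads were expected in EA at the E3 rate and 28 were seen (upper bound 40.5). A mislabelled library is argued against as well, with at most 10 reads in an EA library and at least 13402 in an E3 library. EA had 0.667 reads per CDS over the regions (bounds 0.443 to 0.964), against 0.269 (upper bound 0.555) in a region silent in both strains. The bounds overlap, but an overlap is not a test of a difference. Whether the DNA of the silent region is present is also unknown. The comparison therefore cannot tell transcription that is off with the DNA present from loss of the DNA. A loss in EA or its line, as a hypothesis, stays open because no DNA data were used here.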
